A study of Mus musculus with 15 samples.

How the data were processed

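RNA of sorted brain SMC/pericyte cells (4 Notch3 +/- and 5 Notch3 -/- mice) and of aorta explants (3 arrays per genotype) was hybridised to Affymetrix mouse genome arrays, per the labels and the series' design text. The deposited values are linear probe-set intensity, scaled by the authors to a target of 150 per array with 15 µg of cRNA on each, per the labels and design text; the 2% trimmed mean was 150 on all 15 arrays. That text names Rosetta Resolver for the authors' own comparisons. The algorithm that summarised probes, any background correction and detection calls are not given in the sources used here, and no genome build is named. Brain cells were sorted into the lysis buffer of a column kit, and aorta RNA was extracted with Trizol before its columns, per the labels, so levels across tissues also carry that difference.

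The table held 45101 probe sets, of which 34958 carried 1 gene symbol in the platform annotation, 932 several and 9211 none; probe sets with several or none were tested but not named. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table (assembly GRCm38.p6, used for names and gene neighbours only): 34754 matched and 204 kept the older symbol. Replicates within a group correlated at r between 0.920 and 0.982 with at most 0.00665% of values identical, so each array counted as 1 replicate. Percent of values under 50 was 51.9 and 52.0 in brain and 55.6 and 56.1 in aorta for the +/- and -/- groups.

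Groups came from the sample titles, and the design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Values were taken as log2(value + 16), so fold changes understate those of dim probe sets. The 64 control probe sets were left out, and of the rest those at or above the median mean log2 value of the arrays in the fit were tested (22519 in each comparison). Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment at 5%. Genotypes were compared within the 9 brain arrays and within the 6 aorta arrays, the difference between these differences in 1 fit over 15 arrays, and brain against aorta in the 7 Notch3 +/- arrays. Replicate names are not shared between groups, so no pairing was fitted. The aorta names fall into a 55xx and a 61xx series, which was fitted as a block in an alternative. Brain names A, B, C, D and F are all Notch3 -/-, and E, G, I and H all Notch3 +/-. The titles do not say what the letters mean. If they follow an order of processing, that order nearly coincides with genotype and was not tested.

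In each genotype comparison the named genes were Notch3, then the 12 largest rises and 12 largest falls among genes past 5% with 1 symbol and no overlap of arrays, at the brightest probe set of the gene; where fewer than 10 passed in a direction, the smallest p filled up to 10. Up to 4 members per described list were named by smallest p (by largest difference between tissues), and up to 10 genes for the difference between tissues. Genes outside this rule are said to be so.

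The 31 gene lists were Notch pathway, smooth muscle contractile, pericyte and mural, smooth muscle channels, vasoactive receptors, oxidative phosphorylation, glycolysis, hypoxia, extracellular matrix, basement membrane, TGF-beta and BMP, cell cycle, interferon response, inflammatory cytokines, immediate early and stress, unfolded protein response, cholesterol synthesis, cytosolic ribosome, and markers of endothelium, astrocytes, neurons, oligodendrocytes, microglia and macrophages, fibroblasts, erythroid cells, choroid plexus and ependyma, adipocytes, striated muscle, lymphocytes and Schwann cells, and 1 more that is not reported here. Notch3 was in none. Each was tested on 1 probe set per gene (the brightest) with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move 1 way on balance and compares the list with no other genes. Benjamini-Hochberg adjustment ran over the 31 lists. List scores per array were the mean deviation of members from their tissue mean. They were compared by a two-sided exact permutation test over all 126 splits in brain and 20 in aorta. The smallest possible p is 0.00794 in brain and 0.1 in aorta. In brain a list at that floor passes after adjustment over the 31 lists only if enough other lists share it. The fits were tested on simulated data made from the real arrays' means and spreads. In 22519 brain probe sets, 12% of those changed 1.5-fold, 50% of those changed 2-fold, 82% at 4-fold and 68% at 8-fold were recovered, with 1 false call in 107; at 4-fold and 8-fold the probe sets missed in brain were those whose change put their mean under the filter. In aorta 28%, 56%, 82% and 72% were recovered with 7 false calls in 126. For the difference between tissues 2%, 30%, 68% and 76% were, with 4 false calls in 92. Each simulation changed 50 probe sets at each fold, with noise independent between probe sets. So many calls loosen the adjusted threshold. The shares therefore overstate what would be recovered where few or no probe sets pass, as in aorta.

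Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, the brightest 25% of probe sets, eBayes without trend, array weights, 1 probe set per gene, a threshold of 10%, an unadjusted p under 0.01 with a fold of at least 1.5, all 15 arrays in 1 fit, and each array left out in turn. Added after the data were seen were the fibroblast list without members of the matrix list, the pericyte list without members of the channel and vasoactive lists, the lists for the difference between tissues with only members tested in both, the regroupings of aorta with the brain groups kept, the 3' to 5' ratios as covariates (averaged, and Gapdh and Actb apart), and 2 lists of glucocorticoid-responsive genes with 2 of clock genes. Coordinates are not reported, and gene ontology enrichment was not computed.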

Results

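Gene expression was measured on 15 Affymetrix mouse arrays, each hybridised with RNA from male C57BL6J mice 10 to 12 weeks of age. The mice carried 1 disrupted copy of Notch3 (Notch3 +/-) or no intact copy (Notch3 -/-). Notch3 encodes a receptor of the Notch family that is found mainly in vascular smooth muscle cells and pericytes, the mural cells of blood vessels. Brain cells sorted by FACS and labelled SMC/pericyte were taken from 4 Notch3 +/- and 5 Notch3 -/- mice, 1 array per mouse by the design text, and aorta explants gave 3 arrays of each genotype. No wild-type arrays were analysed here, so every comparison is between no copy and 1 copy of the gene. The series was set up around Notch signalling and stroke, and the comparison in brain asked which transcripts of the sorted cells depend on Notch3. For aorta nothing in the labels says that the arrays came from separate mice, so p-values there measure only the spread between those samples. The number of arrays limits the precision of every value.

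Notch3 itself was lower in every Notch3 -/- array than in every Notch3 +/- array of the same tissue. In brain cells the brighter of its probe sets read 2616 ± 222 (SD, n = 4) in Notch3 +/- and 210 ± 37.1 (n = 5) in Notch3 -/-, a 11.8-fold fall on the log2(value + 16) scale (log2 -3.56, SE 0.16, limma adjusted p = 4.31e-08). The dimmer probe set read 165 ± 14.3 and 38.5 ± 16.2 (log2 -1.77, adjusted p = 0.00325). In aorta the brighter probe set read 401 ± 47.2 and 108 ± 34.1 (n = 3 each; log2 -1.78, SE 0.19), which did not pass after adjustment over all probe sets (limma adjusted p = 0.135; 0.0168 without Notch3 -/- replicate 6167 and 0.000868 with all 15 arrays in the fit). Whether these probes lie inside the targeted part of the gene is not given in the sources used here.

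A small set of transcripts was lower in sorted brain cells without Notch3, 7 of them members of the list of smooth muscle contractile genes. Casq2, the calcium-binding protein of the sarcoplasmic reticulum, fell 3.49-fold, from 714 ± 162 (n = 4) to 193 ± 44.7 (n = 5). Cacna1h, a T-type calcium channel, fell 3.88-fold (317 ± 113 to 67.8 ± 16.7), and Tesc, a calcium-binding protein, fell 4.97-fold (1819 ± 589 to 375 ± 221). Myh11, the smooth muscle myosin heavy chain, fell 3.18-fold (3232 ± 832 to 1036 ± 368), the actin-binding protein Tagln 2.94-fold (3106 ± 443 to 1096 ± 383) and the myosin light chain Myl9 2.37-fold (3330 ± 931 to 1382 ± 298). Adjusted p by limma was 0.0023 for Casq2, 0.0027 for Cacna1h, 0.00641 for Tesc, 0.0208 for Myh11, 0.0204 for Tagln and 0.0233 for Myl9. Lrrc10b (log2 -1.38), the phosphatase Ptp4a3 (-1.24), the orexin receptor Hcrtr1 (-1.46), the epoxide hydrolase Ephx3 (-1.26), the LIM protein Crip1 (-1.25) and Bcas3 (-1.25) fell as well, with adjusted p between 0.0023 and 0.0437; the dimmer probe set of Ptp4a3 did not (-0.14). In all, 32 of 22519 probe sets passed 5%, of which 27 were lower and 5 higher in Notch3 -/-; they stood for 24 lower and 4 higher named genes and 2 probe sets without a gene name. In each of the 32 every Notch3 -/- array lay on 1 side of every Notch3 +/- array, as did 3.3% of all probe sets tested; 2115 had an unadjusted p under 0.05, where chance gives 1126.

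Transcripts that rose in Notch3 -/- brain cells were fewer and mostly dim. The retinoic acid-synthesising enzyme Aldh1a2 rose from 25.2 ± 27.5 (n = 4) to 118 ± 32.6 (n = 5; log2 1.85, limma adjusted p = 0.0415). Itgbl1, an integrin-like protein, rose from 24.4 ± 10.3 to 97.2 ± 33.2 (log2 1.47, adjusted p = 0.0415) and Slfn5, of the Schlafen family, from 295 ± 81.6 to 796 ± 237 (log2 1.37, adjusted p = 0.0233; 0.28 at its dimmer probe set, which did not pass). The fourth, Prss44, passed at 1 of its probe sets (log2 1.79) but not at the brighter one (-0.21), and is named after its values were seen. The next risers by p did not pass: the adhesion molecule Alcam (log2 0.96, adjusted p = 0.0518), Odr4 (0.94), Tlnrd1 (1.09) and Crnkl1 (1.12; 0.0521 each), the peptidase Dpp4 (1.43; 0.0548), the methyltransferase Inmt (1.19; 0.0715) and the chemokine Cxcl2 (1.70; 0.114, arrays overlapping).

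Single arrays set how many brain genes passed. Without Notch3 +/- replicate H, 10 probe sets passed, without G 15, and without Notch3 -/- replicates D and C 14 and 21. Notch3, Tesc, Casq2, Cacna1h, Lrrc10b and Ptp4a3 passed with any 1 array left out. Tagln was lost without G or H, with adjusted p up to 0.0885, and Myh11 without G, H, A or D, with adjusted p up to 0.0889. Aldh1a2 was lost without each array but G (adjusted p up to 0.128), Hcrtr1 without each but F (up to 0.137) and Itgbl1 without G, I, H, A, B, C or D (up to 0.131). Ephx3 was lost without E, G, H, C, D or F, Myl9 without G, H, A, C, D or F, Crip1 without E, H, A, B, C or D, Bcas3 without G, I, H, A, B or C, and Slfn5 without G, I, H, B or C. Without the filter on brightness Myh11 (adjusted p = 0.0537), Myl9 (0.0558), Crip1 (0.0739), Ephx3 (0.0565), Bcas3 (0.0929), Hcrtr1 (0.117), Aldh1a2 (0.114), Itgbl1 (0.114) and Slfn5 (0.0537) did not pass. Hcrtr1 and Aldh1a2 also failed to pass under quantile normalization (0.054 and 0.059), with a pseudocount of 1 (0.0843 and 0.057), without an intensity trend (0.0504 each) and with array weights (0.0533 and 0.109). Bcas3 did not pass with a pseudocount of 1 (0.0505) or without the trend (0.0505), and neither Crip1 (0.0595) nor Myl9 (0.0504) passed without the trend. Of the risers that had not passed, Alcam passed without B (adjusted p = 0.0323), Tlnrd1 and Dpp4 without A (0.0386 and 0.0483), and Inmt and Cxcl2 without E (0.0434 and 0.00871).

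**Figure D1:**
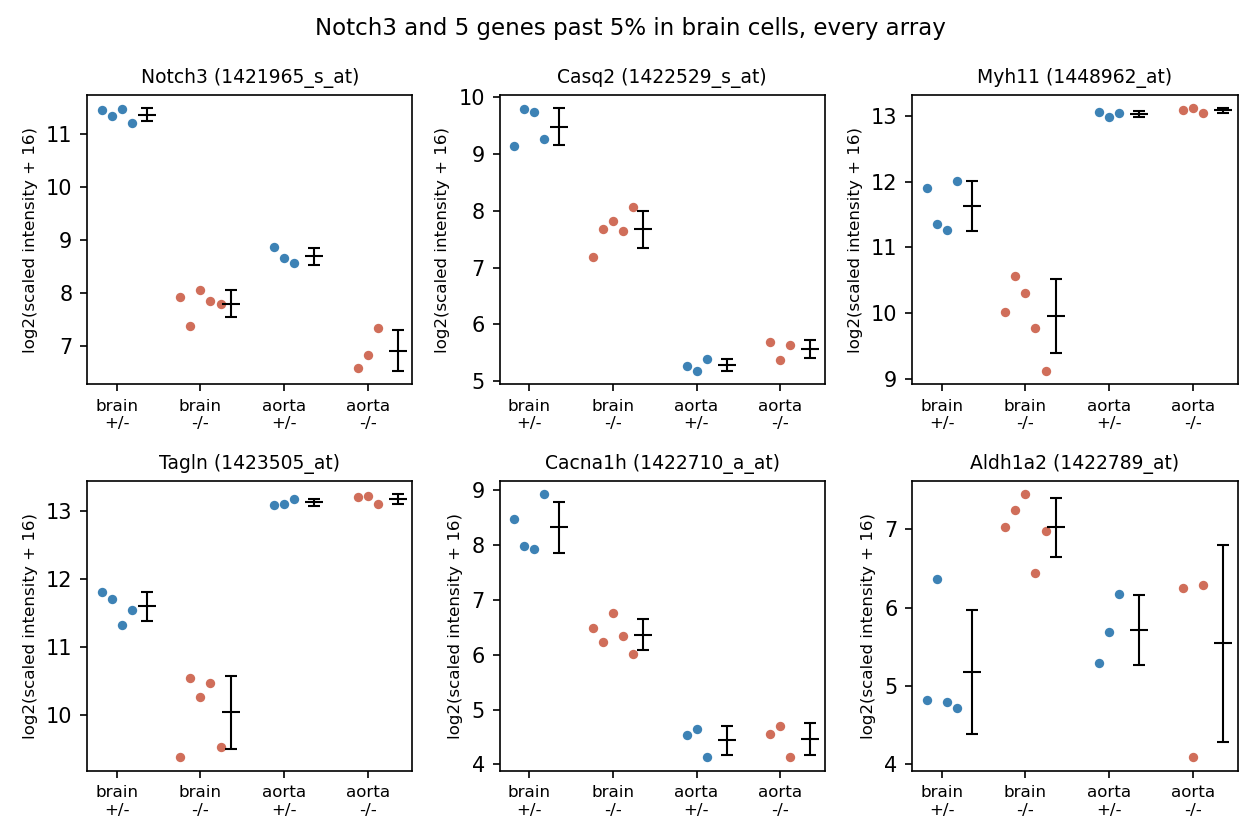
Log2(scaled intensity + 16) of Notch3, Casq2, Myh11, Tagln, Cacna1h and Aldh1a2 on every array, with Notch3 +/- in blue, Notch3 -/- in red, and the mean ± SD of each group as a bar. In brain cells the 5 Notch3 -/- arrays lie below the 4 Notch3 +/- arrays for the first 5 genes and above them for Aldh1a2 (log2 difference 1.85), while Myh11 and Tagln are brighter in aorta and overlap between genotypes there.

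The contractile genes of smooth muscle fell as a group in Notch3 -/- brain cells. Of 33 measured members of the list, 32 were lower in Notch3 -/-, with a median log2 of -0.60 and a mean of -0.70. Over all probe sets tested 7 members passed 5%, and adjusted over the list alone 22 did, all lower. Casq2, Tagln, the cytoskeletal protein Smtn (log2 -1.16) and the actin crosslinker Flna (-1.14) had the smallest p, while the most abundant member, Acta2 (smooth muscle actin), differed by -0.64 without passing over all probe sets (adjusted p = 0.352). The list passed by camera with a preset correlation (adjusted p = 2.06e-26), and adjusted p = 0.0785 with an estimated correlation; fry gave adjusted p = 0.0199. The mean of the list's members per array was lower in every Notch3 -/- array than in every Notch3 +/- array (difference -0.704, SE 0.117). The two-sided exact permutation p was 0.00794, the smallest that 4 against 5 arrays can give, and 0.0615 after adjustment over 31 lists. The channel, vasoactive and Notch pathway lists reached the same floor. Members past 5% over all probe sets numbered 2 without G or without H, 3 without D, and 4 without A or without F; adjusted over the list alone they numbered 20 or 21 with any 1 array left out.

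Ion channels and pumps of smooth muscle, a separate list, also passed lower, with a median of -0.32 over 23 members. Cacna1h was the 1 member past 5% over all probe sets; adjusted over the list alone 3 were, the others being the potassium channel Kcna5 (log2 -0.89) and the sodium pump subunit Atp1b1 (-0.72). P2rx1, an ATP-gated channel, was the next by p (-0.51). Camera gave adjusted p = 7.46e-06 for the list, and adjusted p = 0.126 with an estimated correlation; fry gave 0.0244, and the arrays did not overlap (exact permutation p = 0.00794, 0.0615 after adjustment over 31 lists). The count adjusted over the list alone was 1 without E, G, A, C, D or F, and 5 without I. Pericyte and mural markers had a median of -0.38 over 24 members (camera adjusted p = 9.22e-05; adjusted p = 0.237 with an estimated correlation), with no member past 5% over all probe sets or adjusted over the list alone by limma. Their smallest p belonged to Ndufa4l2 (log2 -0.97), the G-protein regulator Rgs5 (-0.43), the sphingosine phosphate receptor S1pr3 (-0.40) and the transcription factor Foxc1 (-0.43). Without E, 9 pericyte members passed adjusted over the list alone and 1 over all probe sets. Notch pathway genes other than Notch3 had a median of -0.17 over 29 members (camera adjusted p = 0.0209; 0.237 with an estimated correlation; 0.0531 without G, 0.0672 without H). Its array scores did not overlap (exact permutation p = 0.00794, 0.0615 after adjustment over 31 lists). None passed over all probe sets by limma, and 1 adjusted over the list alone, the nuclear receptor-interacting Nrip2 (log2 -1.34); that count was 2 without E or without B, and 1 member passed over all probe sets without I. The Notch target genes Heyl (-0.51) and Hes1 (-0.66) and the scaffold protein Grip2 (-0.54) did not pass. Nrip2 and Grip2 are neither Notch receptors nor ligands, and the list was not tested without them.

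Fibroblast markers rose as a group in Notch3 -/- brain cells. Of 15 measured members 12 were higher, with a median of 0.53 and a mean of 0.49. None passed over all probe sets by limma; adjusted over the list alone 7 were higher and 1 lower. The matrix proteoglycans Dcn (log2 1.20) and Ogn (0.66), the collagen Col3a1 (1.09) and the dipeptidase Dpep1 (1.38) led, and the member that was lower was the glypican Gpc3 (-0.54), named after its value was seen. Camera gave adjusted p = 1.67e-04, with adjusted p = 0.0785 with an estimated correlation, and fry 0.0363. The exact permutation p of the array scores was 0.0238 (0.137 after adjustment over 31 lists), with overlap at Notch3 -/- replicate F. Of the 16 genes on this list 7 are also on the extracellular matrix list, and without them 8 tested members gave a mean of 0.28 and camera adjusted p = 0.363. The higher count adjusted over the list alone was 3 without B and 4 without C or D, and 1 member passed over all probe sets without E. Extracellular matrix genes had a median of 0.17 (camera adjusted p = 0.0209; 0.605 with an estimated correlation), with 0 past 5% over all probe sets by limma and 5 higher adjusted over the list alone: Dcn, Ogn, Col5a2 (1.07), Col14a1 (0.56) and Col3a1. That call was lost without I (0.153), B (0.0994) or C (0.0602).

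Energy and translation genes passed by camera with the preset correlation but not with an estimated one, and rested on single arrays. Oxidative phosphorylation genes had a median of -0.14 over 70 members (camera adjusted p = 3.98e-04; 0.641 with an estimated correlation), led by Uqcrc1 (log2 -0.66) of complex III, and cytosolic ribosomal proteins a median of -0.16 over 33 (0.0194; 0.757 with an estimated correlation; 0.136 without C), led by Rplp0 (-1.13). Array scores of the genotypes overlapped for both (exact permutation p = 0.27 and 0.341), and without H the mean went from -0.156 to -0.0526 for oxidative phosphorylation (camera adjusted p = 0.395) and from -0.158 to -0.026 for the ribosome (0.941). No member of either list passed over all probe sets or adjusted over the list alone by limma. Glycolysis genes had a median of -0.10 over 18 (camera adjusted p = 0.0209; 0.246 with an estimated correlation), with 0 members past 5% over all probe sets and 3 lower adjusted over the list alone: the aldolase Aldoa (-0.83), the lactate transporter Slc16a1 (-0.61) and the lactate dehydrogenase Ldha (-0.53). Inflammatory cytokine genes had a median of 0.30 over 19 (0.0299; 0.432 with an estimated correlation), with 0 past 5% over all probe sets and Cxcl2 alone past 5% adjusted over the list alone. The glycolysis call was lost without G, I, A or C (adjusted p up to 0.0673), and the inflammatory call without I, H, A, B or C (up to 0.227).

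Endothelial markers differed little between genotypes, with a median of -0.05 over 23 members (camera adjusted p = 0.523; exact permutation p = 0.54 for the array scores). Markers of the other cell types a brain sort could hold did not pass either: camera adjusted p was 0.751 for astrocytes, 0.939 for neurons, 0.0648 for oligodendrocytes, 0.751 for microglia and macrophages, 0.939 for choroid plexus and ependyma, 0.0684 for erythroid cells (2 members tested), 0.0691 for adipocytes, 0.939 for striated muscle, 0.898 for lymphocytes and 0.38 for Schwann cells. Nor did vasoactive receptors (0.0648), hypoxia genes (0.523), basement membrane (0.346), TGF-beta and BMP signalling (0.939), cell cycle (0.964), interferon response (0.751), immediate early and stress genes (0.0684), the unfolded protein response (0.616) or cholesterol synthesis (0.939). The array scores of vasoactive receptors did not overlap, however (difference -0.14, SE 0.0441; exact permutation p = 0.00794, 0.0615 after adjustment over 31 lists). No member of these lists passed over all probe sets by limma. Adjusted over the list alone, 2 basement membrane genes were lower (the laminin Lama5, log2 -0.67, and the integrin Itga7, -0.71), as were 2 in TGF-beta and BMP signalling (Tgfb3, -1.31, and Id3, -0.56). Among the cell type markers S100b (0.75), Bpgm (0.64), Tmem212 (0.66) and Ccdc153 (1.44) were higher and Rarres2 (-0.85) and Pnpla2 (-0.63) lower by that count. Median, mean and camera differed in sign for cell cycle, cholesterol synthesis, choroid plexus, striated muscle and lymphocytes.

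**Figure D2:**
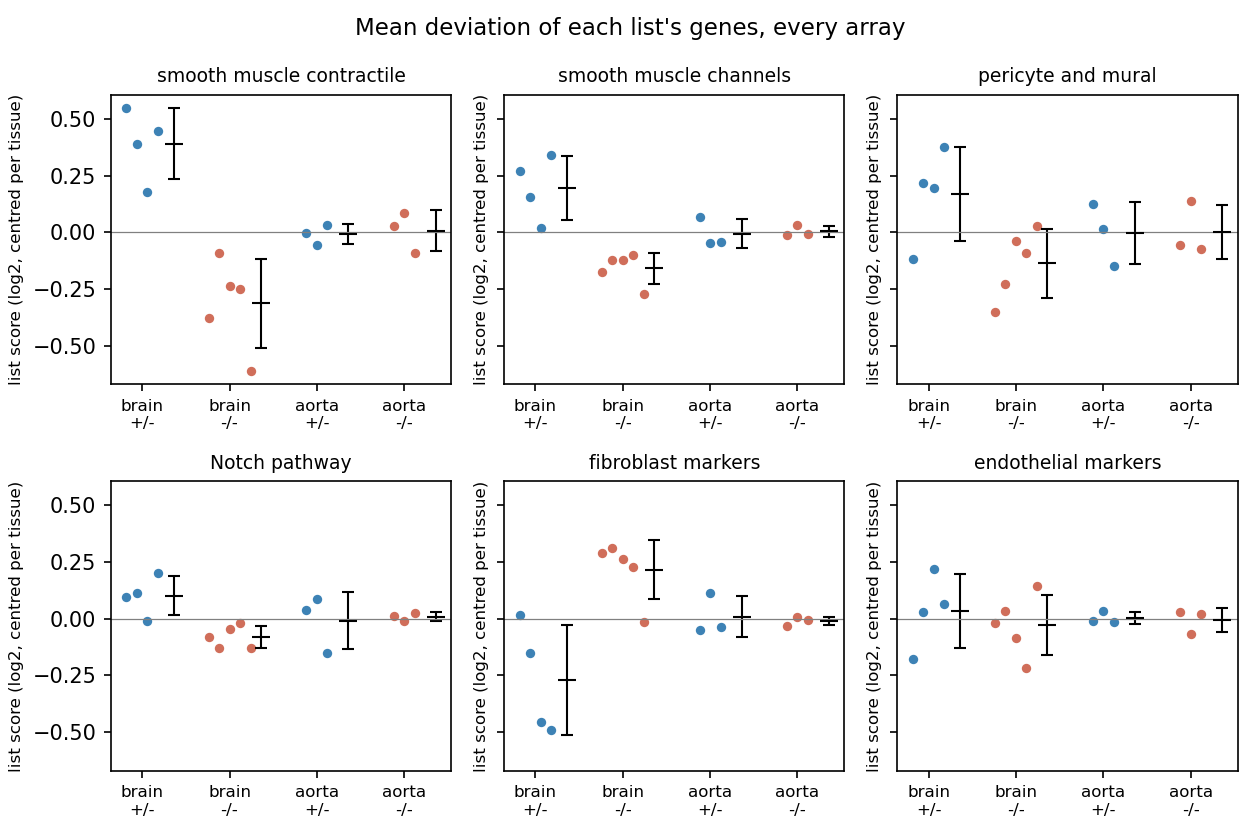
Mean log2 deviation of each list's genes from their tissue mean on every array, for 6 gene lists, with Notch3 +/- in blue, Notch3 -/- in red and the group mean ± SD as a bar. In brain cells the contractile scores of the 5 Notch3 -/- arrays lie below those of the 4 Notch3 +/- arrays (difference -0.704) and the fibroblast scores lie higher on average (0.487), while endothelial scores and all 6 aorta panels overlap.

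In aorta no transcript passed 5% between genotypes: limma called 0 of 22519 probe sets, with 980 at an unadjusted p under 0.05 where chance gives 1126. Groups did not overlap at 9.47% of probe sets, where chance gives 10% for 3 against 3. The smallest p after Notch3 belonged to the metallothionein Mt1, at 1683 ± 286 (n = 3) in Notch3 +/- and 745 ± 66.4 (n = 3) in Notch3 -/- (log2 -1.15, SE 0.13, limma adjusted p = 0.135). The other transcripts lower in Notch3 -/- with the smallest p were Timp4 (-0.97), Tcim (-1.27), the stress-response gene Ddit4 (-1.30), the kinase Sgk1 (2124 ± 524 to 1028 ± 39.6), Mt2 (-1.34), the cell cycle inhibitor Cdkn1a (-0.78), Slc10a6 (-0.55), Angptl4 (-0.93) and Arrdc3 (-1.41). Those higher were Zfp516 (0.77), the ephrin Efnb2 (0.45), the small GTPase Rrad (1.03), Eid1 (0.36), Zfp36l1 (0.40), Inmt (0.88), the Wnt receptor Fzd5 (0.43), Rbbp9 (1.04), the matrix protein Fmod (0.62) and Pcolce2 (0.44). None of these passed, with adjusted p between 0.135 and 0.745. Without Notch3 +/- replicate 5556, 7 probe sets passed, among them Mt1, Sgk1 and Mt2 (adjusted p = 0.0108 each). Without Notch3 -/- replicate 6167, 7 passed as well, among them Notch3 and Rbbp9 (0.0168 each), and 1 passed without Notch3 -/- replicate 5559.

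The contractile genes that were lower in brain did not differ in aorta, with a median of 0.01 over 33 members (camera adjusted p = 0.578). Adipocyte markers were lower in Notch3 -/- aorta, with a median of -0.31 over 14 members (camera adjusted p = 0.00625; 0.931 with an estimated correlation), and 0 passed 5% over all probe sets or adjusted over the list alone by limma. Leptin (Lep, log2 -0.60), resistin (Retn, -0.68), Fabp4 (-0.39) and Cidec (-0.65) had the smallest p. Striated muscle markers were lower too, with a median of -0.27 over 7 members (camera adjusted p = 0.0468; 0.647 with an estimated correlation); 0 passed over all probe sets and 2 adjusted over the list alone, cardiac actin Actc1 (-0.92) and cardiac myosin Myh6 (-1.50). The adipocyte call was lost without 5556, 6166, 5558 or 5559 (adjusted p up to 0.536), where the mean of -0.302 became -0.122, -0.151, -0.222 and -0.194. The striated muscle call was lost without each but 5556 (up to 0.393), and its mean of -0.464 became -0.187 without 6166. No other list passed in aorta; the next were hypoxia (median -0.10), oxidative phosphorylation (-0.04) and erythroid markers (0.43), at camera adjusted p = 0.0606 each. Adjusted over the list alone, Ddit4 was lower among hypoxia genes, Nfkbia (-0.73) and Cxcl12 (-0.72) among inflammatory genes and Cdkn1a among cell cycle genes, and Mcm2 (0.67) and Bpgm (0.36) were higher. Median, mean and camera differed in sign for channels, inflammatory, immediate early, endothelial, microglia and fibroblast lists.

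The genotype difference itself differed between brain and aorta for 4 probe sets in the 15-array fit (1071 at an unadjusted p under 0.05). Casq2 fell in brain and read 22.9 ± 2.81 and 31.6 ± 5.28 in aorta (n = 3 each), a difference between tissues of -2.09 (SE 0.29, limma adjusted p = 0.0117); it was so dim in aorta (array median 39) that a fall as large as in brain could not have been seen there. The log2 fall of Notch3 was larger in brain (-1.78, adjusted p = 0.0117 by limma). Its Notch3 -/- readings were 210 in brain and 108 in aorta, so it was not dimmer in brain. The larger fall came with a brighter Notch3 +/- reading (2616 against 401). Depp1 read 1887 ± 210 and 2309 ± 468 in brain but 74.3 ± 37.4 and 8.15 ± 0.776 in aorta (difference 2.10, adjusted p = 0.0117); the size of that difference rests on dim aorta values, and with a pseudocount of 64 it was 1.17 and did not pass (adjusted p = 0.173). Rrad went in opposite directions, at 1927 ± 465 and 1086 ± 168 in brain and 726 ± 161 and 1500 ± 346 in aorta (-1.83, adjusted p = 0.0212; 0.0638 without an intensity trend). Cacna1h (-1.98, adjusted p = 0.137; too dim in aorta for a fall to be seen), the glutamine synthetase Glul (1.34), Tesc (-2.40), Crnkl1 (1.43), Tagln (-1.61) and Flna (-1.13) came next and did not pass. Without aorta Notch3 +/- replicate 6166 none of the 4 passed, without 5561 or without Notch3 -/- replicate 5558 only 1 did, and without Notch3 +/- replicate 5556 there were 7. Rrad was also lost without brain Notch3 +/- replicate E, Notch3 -/- replicate D or aorta replicate 6167, and Tesc passed without brain Notch3 -/- replicate B (adjusted p = 0.0121).

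By gene list, the genotype difference of the contractile genes was more negative in brain than in aorta, with a mean difference of -0.717 and all 33 members negative; 1 passed over all probe sets and 11 adjusted over the list alone (camera adjusted p = 8.39e-25; 0.0615 with an estimated correlation; fry 0.0384). Channels (-0.372; 0.0729 with an estimated correlation), pericyte markers (-0.272; 0.256), vasoactive receptors (-0.177; 0.256), the Notch pathway (-0.186; 0.257) and oxidative phosphorylation (-0.102; 0.862) also passed by camera in that direction. Fibroblast markers (0.481; 0.0729), inflammatory genes (0.297; 0.407) and extracellular matrix (0.213; 0.549) passed in the opposite direction. Members too dim to be tested in aorta, such as the pericyte markers Slc6a20a (4.41 in Notch3 +/- aorta, array median 39) and Atp13a5 (6.65), only repeat the change in brain. With only members bright enough to be tested in both tissues, an alternative added after the data were seen, the contractile list (32 members, mean -0.674), channels (19, -0.315), pericyte markers (15 of 24, -0.294), vasoactive receptors (18, -0.218), fibroblast markers (14, 0.497) and extracellular matrix (37, 0.215) still passed by camera. The Notch pathway (-0.145, adjusted p = 0.142), oxidative phosphorylation (0.055) and inflammatory genes (0.19; 0.142) did not. With an estimated correlation none passed there (smallest adjusted p = 0.117). In these 8 lists no member passed over all probe sets by limma. Adjusted over the list alone, Cacna1h passed among channels, where its aorta readings of 5.91 and 6.37 were too dim to show a fall, and Dcn (1.14), Ogn (0.68) and Dpep1 (1.71) among fibroblast markers, and in lists that did not pass Ddit4 (1.58) and the immediate early gene Ier2 (-0.96) did. Single arrays ended 5 of the list calls: the Notch pathway without brain G, H, A, B, C or F or aorta 5556, 6166, 5558 or 6167 (adjusted p up to 0.172), vasoactive receptors without E, G, A, B, F, 5561, 6166 or 6167 (up to 0.195), oxidative phosphorylation without H, A, C, 5561, 5558 or 6167 (up to 0.942), extracellular matrix without I, B, C, D, 5561, 6166, 5558 or 6167 (up to 0.145) and inflammatory genes without I, H, A, B, C, 6166, 5559 or 6167 (up to 0.159). Across 19397 probe sets tested in both tissues, the log2 differences in brain and aorta correlated at Pearson's r = 0.0751 (permutation p = 0.23); genes are not independent replicates. Of 21 probe sets past 5% in brain, Notch3 aside, that were tested in aorta, 11 had the same sign there, and their median absolute log2 difference was 0.0871 in aorta against 1.25 in brain.

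**Figure D3:**
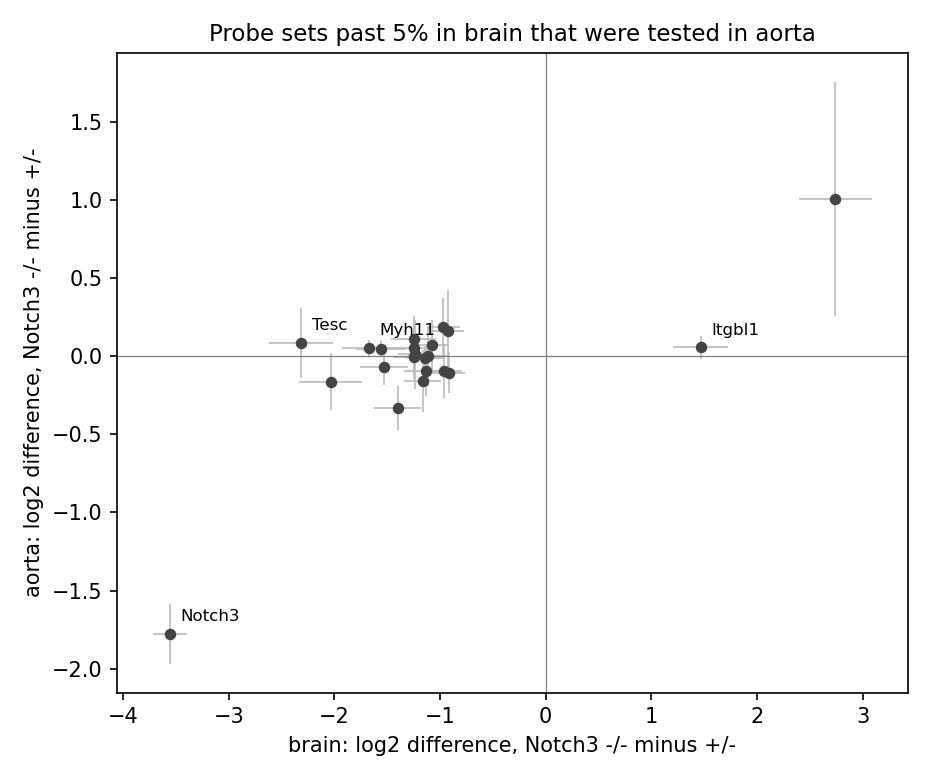
Log2 difference between Notch3 -/- and Notch3 +/- in brain cells (x axis) and in aorta (y axis) for the 22 probe sets past 5% in brain that were tested in aorta, with bars of 1 SE. Notch3 lies at -3.56 and -1.78, and most others lie near 0 on the aorta axis; the rightmost point (brain 2.74) has no gene name.

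The sorted brain cells and the aorta differed widely in the cell markers they held. In Notch3 +/- mice 11661 of 22519 probe sets differed between brain cells and aorta, 5976 higher and 5685 lower in brain; at 11152 of these the 4 brain and 3 aorta arrays did not overlap. Pericyte markers were higher in brain (median 1.46, 19 of 24 higher past 5%), led by Vtn (log2 8.14), Slc6a20a (6.36), S1pr3 (6.01) and Zic1 (5.88). Mcam (-2.24), Abcc9 (-1.43) and Tbx18 (-1.54) were lower. Contractile genes were lower (median -1.45, 27 of 34 lower past 5%, camera adjusted p = 8.42e-07), Cnn1 (-3.58) and Synpo2 (-3.36) among them. Past 5%, 5 were higher: Casq2 (4.20) and Pln (3.98), both regulators of the sarcoplasmic reticulum, Des (1.85), Acta2 (0.80) and Cald1 (0.51). Matrix genes were lower in brain (median -2.76, 34 of 39, with Col8a1 and Sparcl1 higher), as were fibroblast (-3.21, with Slc6a13 and Igf2 higher) and adipocyte markers (-2.14), led by Dpt (-6.81) and Fabp4 (-7.09). Markers of brain cells other than mural cells were abundant in the sorted cells. Endothelial markers were higher than in aorta (median 2.86, 21 of 23, with Pecam1 and Erg lower), with Slco1a4 (8.80) first and the tight junction gene Cldn5 at 15991 ± 4629 (n = 4) against 354 ± 29.1 (n = 3). So were astrocyte (median 3.83; Aldoc 6.78, Aqp4 5.38), oligodendrocyte (2.28; Mobp 8.21, Mbp 7.39), choroid plexus (2.39; Ttr 10.12, Kcne2 4.30) and neuron markers (1.28; Camk2a 4.41), which all passed by camera with adjusted p at or below 0.0213. Immediate early (median 1.98), interferon (1.86) and inflammatory genes (1.61) were also higher in the sorted cells. Members that went against their list were named after their values were seen. With an estimated correlation none of these lists passed, the smallest adjusted p being 0.0823. Tissue here coincides with sorting and RNA extraction, so these cannot be told apart. The mean log2 3' to 5' ratio of the Gapdh and Actb controls also differed, at 4.91 in Notch3 +/- brain and 1.78 in Notch3 +/- aorta. Levels of single probe sets may carry that difference too.

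No sign of RNA quality passed 5% between genotypes, which with so few arrays does not show that quality was alike. In brain the log2 3' to 5' ratio of the Gapdh control was 4.41 ± 0.252 (n = 4) and 4.14 ± 0.227 (n = 5; exact permutation p = 0.135), and that of Actb 5.40 ± 0.521 and 5.67 ± 0.12 (exact permutation p = 0.333). In aorta the mean of both ratios was 1.78 ± 0.133 and 1.75 ± 0.0158 (n = 3 each), far below the 4.91 of brain. Of 10 such measures per tissue, the lowest p after Benjamini-Hochberg adjustment was 0.61 in brain and 0.8 in aorta. In aorta 3 against 3 arrays cannot give an exact p below 0.1. Before adjustment the lowest exact permutation p in brain was 0.0952, for the Actb log2 3' to middle ratio (2.7 ± 0.266 and 3.06 ± 0.265). Hybridisation spike-ins in aorta did not overlap, at log2 11.06 to 11.09 in Notch3 +/- and 11.16 to 11.37 in Notch3 -/- (exact permutation p = 0.1). Brain Notch3 +/- replicate H stood apart in its hybridisation spike-ins, which read 1.95 times the mean of the other brain arrays (others between 0.841 and 1.14).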

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

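The test of Ephx3 and Cacna1h in aorta, the fit with the 3' to 5' ratios as covariates, the fibroblast and pericyte lists without members of other named lists, the lists with only members tested in both tissues, the regroupings with the brain groups kept, the comparison of Csrp2 with markers of other cells and the held-out list of glucocorticoid-responsive genes were chosen only after the result concerned was seen, and the clock and number-series tests after the glucocorticoid pattern was seen.

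Notch3 -/- brain cells differed from Notch3 +/- brain cells at 32 probe sets, and chance is an unlikely source of that count. Of 100 splits of the 9 arrays (126 are possible) only the real one gave as many, and the highest other gave 3. This does not cover each probe set, and the count ran from 10 to 38 with any 1 array left out. Nor can the splits tell genotype from the order of the brain names, which nearly follows the same grouping. A second concern is DNA of the strain in which Notch3 was targeted, which can stay around the gene after backcrossing and alter or hide neighbouring transcripts. Of 28 called probe sets with a position, Notch3 aside, 2 lay within 20 Mb of it (7.14%, against 3.25% of those tested). Fisher's exact test gave a one-sided p = 0.231, but with 2 calls there it cannot exclude an excess. All but those 2 lay outside that stretch, which argues against such DNA as the source of the calls as a whole. For those 2, Ephx3 (2 genes from Notch3) and Cacna1h (240 genes), it cannot be told apart from an effect of Notch3, because aorta, where the same DNA would act, expresses them too weakly to test (highest mean 20.1, array median 39). An effect of losing Notch3, untested beyond the genotype itself, stays open for the rest.

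The contractile genes were lower in Notch3 -/- brain cells (difference of the score -0.704, SE 0.12). Uneven RNA quality, as far as the 3' to 5' ratios measure it, is argued against as the whole source. With the 3' to 5' ratios of Gapdh and Actb as separate covariates the difference was -0.615 (SE 0.0944). Their average, alike in both genotypes (4.91 each), could not move the difference. The score followed the Gapdh ratio (slope 0.533, SE 0.176), which was lower in Notch3 -/- (4.14 against 4.41). A part of the difference may therefore come from RNA quality. The Actb 3' to middle ratio (2.7 in Notch3 +/- and 3.06 in Notch3 -/-, exact permutation p = 0.0952) was not fitted as a covariate. More cells of another type met their prediction. Of 7 marker lists the fibroblast list was higher in Notch3 -/- (0.487, exact permutation p = 0.0238 before adjustment). Much of that rise lay in genes shared with the matrix list. Without them its 8 tested members gave a mean of 0.28 and did not pass (camera adjusted p = 0.363). Added cells of 1 type would lower the markers of all other types alike. Endothelial (-0.0622, SE 0.101), oligodendrocyte (0.197, SE 0.152) and microglia scores (0.0517, SE 0.177) showed no such fall. Astrocyte (0.059, SE 0.357), neuron (-0.0254, SE 0.234) and choroid scores (0.0393, SE 0.354) did not either. This argues against such cells as the whole source, and a part stays open. Fewer mural cells of every kind stay open, since the contractile and pericyte scores parted by -0.400 (SE 0.200, exact permutation p = 0.0556). Without the pericyte members on the channel and vasoactive lists they parted by -0.384 (SE 0.209). A smaller share of arterial smooth muscle against pericytes cannot be told apart from lower expression per cell. Members past 5% over the list alone spread over 1.43 (Casq2 -1.80, Csrp2 -0.37, SE 0.251). That is more than 1 share allows if no other cell in the sort holds these genes. The pair is the largest and the smallest fall, picked by value, so its SE understates the chance spread. Transcripts of other cells were in the sort (Ttr of the choroid plexus read 28772, Csrp2 1160 in Notch3 +/-), though a reading does not show that whole cells were. Such cells, if sorted, may keep up a member such as Csrp2. Readings of different probe sets cannot be compared, however, and whether those cells hold Csrp2 was not measured. An effect of Notch3 on these genes within each cell was not tested and stays open.

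Genes that glucocorticoids induce were low in Notch3 -/- aorta. Of 12 such genes noticed among the smallest p there or in the difference between tissues (Mt1, Mt2, Sgk1 and Ddit4 among them), all were lower, with a mean of -1.10, which is no independent test. A second list of 12, without those, was lower as well (-0.734, SE 0.178), in 3 of 3 Notch3 -/- arrays below every Notch3 +/- array. It was scored on the same arrays that prompted the idea, so it is no independent test either. The exact permutation p was 0.1, the smallest 3 against 3 can give. Camera with an estimated correlation gave p = 0.0144 before adjustment. Adjusted over the 4 lists added after the data were seen, and not over the 31, it was 0.0289. Those 4 include the first list, taken from these same values, which lowers the adjusted value. The second list was led by Errfi1 (-1.43), Zbtb16 (-1.53), Per1 (-1.03) and Fkbp5 (-0.88). By limma 9 of its 12 members passed 5% adjusted over the list alone and 0 over all probe sets. A different time of day at collection cannot be told apart from it: clock scores overlapped (dusk minus dawn -0.194, SE 0.266, exact permutation p = 0.5; dusk genes -0.19, dawn genes 0.01), too wide a spread to exclude a shift. The number series is argued against, since the difference held within 55xx (-0.567) and between the single 61xx arrays (-1.07). Lower glucocorticoid exposure of these mice, by handling, stress or genotype, is a candidate explanation that may account for it, but adipocyte markers (median -0.31, 13 of 14 lower, arrays overlapping) and striated muscle markers (-0.27, arrays not overlapping) were low in the same arrays, so a different share of tissues in the explants was not excluded; in brain the held-out list differed by -0.01 and the first by 0.25 (exact permutation p = 0.937 and 0.0635).

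The genotype difference differed between brain and aorta, by a test of the difference itself, for Casq2 (-2.09), Notch3 (-1.78), Depp1 (2.10) and Rrad (-1.83); Casq2 was too dim in aorta for a fall as large as in brain to be seen there, and Depp1 did not pass with a pseudocount of 64 (1.17, adjusted p = 0.173). Of 100 regroupings of genotype within tissue, 2 gave as many as the real 4, the real one included, but most of these also break up the brain groups and so take away the brain effect. With the brain groups kept, 6 of the 20 groupings of the aorta arrays gave as many, the real one included, so whether the count owes anything to genotype in aorta cannot be told. The highest other, 10, set aorta arrays 5561, 5558 and 5559 against 5556, 6166 and 6167, which points to a structure among the aorta arrays. That grouping nearly follows their number series. The log2 18S rRNA signal, looked at after the grouping was seen, parted the same way without overlap (8.56 to 9.12 against 9.89 to 10.51). Which of these the structure reflects was not tested. By gene list, each by camera with the preset correlation and none with an estimated one (smallest adjusted p = 0.0615), the difference was -0.717 for contractile genes, -0.372 for channels, -0.272 for pericyte markers, -0.186 for the Notch pathway, -0.177 for vasoactive receptors, -0.102 for oxidative phosphorylation, 0.213 for extracellular matrix, 0.297 for inflammatory genes and 0.481 for fibroblast markers. In aorta alone the real grouping gave 0 probe sets by limma (980 at an unadjusted p under 0.05), a count that each of the 10 possible splits reached; the highest other, 11, came from that same grouping of aorta arrays; 10 splits are too few for a share under 0.05, and with the number series as a block the count was 0. Between brain and aorta the real grouping gave 11661, reached by 1 of 35 splits, the highest other giving 7. That is the smallest share 35 splits can give, and it makes chance an unlikely source of that count.

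Single brain arrays stood far from the rest of their group in 9 of 136 groups of values examined, where chance gives about 1 in 20. In Notch3 -/- these were replicate A for the dimmer Notch3 probe set (66.6, others 26.7 to 37.5), B for Tesc (765, others 251 to 338), and F for the fibroblast score (-0.0123, others 0.229 to 0.313). In Notch3 +/- they were G for Aldh1a2 (66.4, others 10.3 to 12.3), I for the basement membrane score (-0.126, others 0.0843 to 0.0966), E for the interferon score (-0.458, others 0.0953 to 0.206) and the lymphocyte score (0.202, others -0.0382 to -0.000655), and H for the Schwann cell score (-0.244, others -0.0529 to -0.0213) and the array mean (294, others 254 to 260).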

How the results depend on the processing

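The lists without members of other named lists, the lists of members tested in both tissues and the 3' to 5' covariates were added after the data were seen. The brighter Notch3 probe set in brain ran from -3.30 to -3.65 and passed in every setting tried; in aorta, with any 1 array left out, it ran from -1.99 (passed without 6167) to -1.61. The 32 brain probe sets became 50 with a pseudocount of 64 and 52 with array weights, 18 without the filter, 62 at 10%, 137 with 15 arrays in the fit, 477 by the looser rule (p under 0.01, fold of at least 1.5), and 10 to 38 with any 1 array left out; 29 were shared under quantile normalization (34 in all). In aorta the count by limma was 2 with 15 arrays in the fit, 114 by the looser rule and 0 to 7 with 1 array left out, and 0 in the other settings. For the difference between tissues it was 13 with array weights and 0 to 7 with 1 array left out. Between tissues it was 6963 in the brightest 25% and 6586 with 1 probe set per gene, where fewer were tested. With an estimated correlation 0 lists passed in brain (10 with the preset), 0 in aorta and 0 for the difference between tissues, and the contractile list, at -0.704, had adjusted p = 0.0785. Lists past 5% with 1 array left out numbered 6 to 13 in brain (6 without C), 0 to 6 in aorta (4 under quantile normalization; 6 without 5561, 5 without 6167, 0 without 6166, 5558 or 5559) and 5 to 10 for the difference between tissues (5 without A, C or 6167). With the mean of each gene's probe sets, 12 lists passed by camera in brain, 2 in aorta and 6 for the difference between tissues. With the brightest probe set these were 10, 2 and 9. The correlation between tissues ran from 0.0071 to 0.116 with 1 array left out. Other than leaving out arrays, named brain genes kept their side of 5% in 203 of 252 values (21 lost, 28 gained), aorta genes in 250 of 251 and genes for the difference between tissues in 98 of 106; none reversed. Where settings differed, the cause was not tested.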

Other observations

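The genes in this part were singled out after their values were seen. Casq2 was far brighter in the brain preparation than in aorta: it read 714 ± 162 in Notch3 +/- brain cells (n = 4) and 22.9 ± 2.81 in Notch3 +/- aorta (n = 3), whereas Acta2 read 20581 ± 6852 and 11415 ± 484. Markers of cells outside the mural lineage were bright in the sorted cells of both genotypes: Mbp of myelin read 27525 ± 7413 and 26953 ± 3173, Ttr of the choroid plexus 28772 ± 11080 and 23131 ± 3172, and Cldn5 of endothelium 15991 ± 4629 and 15019 ± 1480 (Notch3 +/-, n = 4; Notch3 -/-, n = 5). Itgbl1, which rose in Notch3 -/- brain cells, read 3311 ± 177 and 3452 ± 239 in aorta. Inmt was higher in Notch3 -/- in both tissues without passing in either (log2 1.19 in brain and 0.88 in aorta).

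Of the called probe sets outside the rule for named genes, Crispld2 passed at a pair of probe sets (log2 -2.03 and -1.53) while its brightest did not (-1.68, limma adjusted p = 0.0546), Usp2 passed only at its dimmer probe set (-1.18; the brighter -0.32, adjusted p = 0.668), and the unnamed probe sets moved by 2.74 and -1.40.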
